A study of Mus musculus with 12 samples.

How the data were processed

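RNA of 12 mouse libraries was measured: wild-type ESC, wild-type EpiLC, Sirt1KO ESC and Sirt1KO Otx2KD ESC, with 3 replicates each, grouped by the sample titles. Per the labels' protocols, RNA was extracted with Trizol, selected with oligo-dT and made into TruSeq libraries. ESC grew on gelatin in serum-free N2B27 with LIF and the MEK and GSK3 inhibitors, and EpiLC were induced on fibronectin. The labels do not say how Otx2 was knocked down. Per the submitters' processing notes, reads were aligned to mm9 with TopHat and quantified with Cufflinks and Cuffdiff, of which no versions are given. The deposited values are FPKM per locus as the authors computed them, and how they set library sizes is not stated. Coordinates are those of the deposited files, taken as mm9.

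Each library file held 27914 loci, of which 23136 carry a gene name. The 4778 unnamed loci, which are mostly short, hold between 95.3% and 96.9% of the FPKM sum of a library, so they were left out of the tests and of any share of totals, and entered an alternative. Named loci with FPKM of at least 1 in at least 3 of the 12 libraries were tested (12320). Of these, 191 loci carry merged names and 141 share a symbol with another locus.

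No counts or read totals are given, so relative depth was estimated from the FPKM that a fragment adds. Over named loci under 0.1 FPKM in both libraries, the most frequent ratio of each library to wild-type ESC replicate 1 was taken as the ratio of their values for a fragment. On this scale 3441 of 15967 loci (21.6%) held whole multiples of a step, where several step sizes were tried per locus. The margin was 0.02 for small multiples and grew in proportion for larger ones, up to 60 fragments. Depth relative to wild-type ESC replicate 1 was 1.00, 0.986 and 1.02 in wild-type ESC and 1.08, 1.33 and 0.888 in EpiLC. It was 1.05, 1.20 and 1.16 in Sirt1KO and 1.31, 0.767 and 1.08 in Sirt1KO Otx2KD, in order of replicate. Spread between replicates over counting noise was taken from 2017 such loci by chi-square, of which 1963 to 1993 had fragments in a given pair. No library files were identical.

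Values were log2(FPKM + 1), and a model with a mean per group was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust, 8 residual degrees of freedom). The comparisons were EpiLC and Sirt1KO with wild-type ESC, Sirt1KO Otx2KD with Sirt1KO and, as a secondary comparison, Sirt1KO Otx2KD with wild-type ESC. Calls used a Benjamini-Hochberg adjusted p under 0.05. Comparisons, gene lists and all alternatives but those on unnamed loci, on shifted chromosomes and on lists under quantile normalization or with a library left out were fixed before the data were examined. On normal data simulated from the overall gene means and residual spread of these libraries, with 200 of 12320 genes changed, changes of 0.25, 0.5, 1 and 2 log2 units were called in 28%, 78%, 96% and 98% of genes for EpiLC, and in 36%, 70%, 100% and 96% for Sirt1KO. For Sirt1KO Otx2KD against Sirt1KO the shares were 36%, 72%, 98% and 94%, and against wild-type ESC 40%, 80%, 100% and 96%. Between 5.66% and 6.83% of the calls were false. In the data, 53.9% to 74.6% of genes were called per comparison, which makes the Benjamini-Hochberg cutoff less strict than in these simulations. The simulated shares therefore do not give the recovery in the data.

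Genes were named by rule: Sirt1, Otx2 and Pou5f1; the 10 genes up and 10 down with the largest fold changes among those called, with libraries that do not overlap and a mean FPKM of at least 5 in the higher group; and up to 4 members of each list with the largest t. Predicted genes, pseudogenes, small RNA genes and duplicated symbols were left out of the top genes. The 29 lists, written from general knowledge, covered naive, primed and formative, general, LIF-STAT3, FGF-ERK, Wnt and beta-catenin, Nodal and Activin, BMP, mesendoderm, neuroectoderm, primitive endoderm, trophoblast, germline, imprinted, DNA methylation, p53, retinoic acid, methionine and one-carbon, glycolysis, oxidative phosphorylation, cholesterol, integrated stress response, sirtuin, fibroblast and feeder, epithelial, mesenchymal, Hox, 2-cell-like and mitochondrially encoded genes. The last 2 had 0 tested members. The other 27 were tested with camera at its preset inter-gene correlation of 0.01, with the estimated correlation as an alternative and with fry, adjusted over the lists of a comparison. Chromosomes were tested with camera in the same way.

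Effects were compared across genes by Pearson and Spearman correlation and by counts of shared calls, beside counts for independent lists and 100 simulations of unchanged groups that share libraries. The position of a library rests on the genes called in EpiLC with a change of at least 1 log2 unit. It is the mean log2 value of those higher minus the mean of those lower. This difference is scaled to 0% at the wild-type ESC mean and 100% at the EpiLC mean. GC content and transcript length came from GENCODE annotation of GRCm38 by gene name. Alternatives covered the pseudocount (0.1), the filter, median-of-ratios and quantile scaling, fits of the 2 groups alone, a replicate block, a fold minimum, gene classes, the variance model, leaving out each replicate, unnamed loci and the shifted chromosomes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for depth, sequence content and figures.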

Results

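Polyadenylated RNA was sequenced from 12 libraries of C57 Bl/6J mouse pluripotent cells in 4 groups of 3: wild-type embryonic stem cells (ESC), wild-type epiblast-like cells (EpiLC), Sirt1 knockout ESC (Sirt1KO) and Sirt1 knockout ESC with Otx2 knocked down (Sirt1KO Otx2KD). ESC resemble the epiblast before implantation and were held in this naive state with LIF, the MEK inhibitor PD0325901 (1 uM) and the GSK3 inhibitor CHIR99021 (3 uM), per the labels' protocols. EpiLC resemble the epiblast after implantation and were made over 48 h with Fgf2 (12 ng/ml), Activin A (20 ng/ml) and a serum replacement (1%). The series sets out to compare the changes of this naive to primed transition with those after loss of Sirt1 and knockdown of Otx2. The deposited values are FPKM, and no fragment counts are given. From the smallest steps between low FPKM values, the depth relative to wild-type ESC replicate 1 ranged from 0.767 in Sirt1KO Otx2KD replicate 2 to 1.33 in EpiLC replicate 2. Between 15775 and 16408 of the 23136 named loci had a value above 0 per library, and 12320 entered the tests. In loci with few fragments (1963 to 1993 per pair), the mean chi-square per locus between replicates, which is 1 for counting noise alone, lay between 1.07 and 1.36 over the 12 replicate pairs. Such loci say little about the spread of abundant genes. The labels do not say whether replicates come from separate cultures, so every p-value here measures only the spread between these samples, which may be technical. FPKM levels are means ± SD and log2 fold changes are ± SE, with n = 3 libraries per group. Fold changes are on the log2(FPKM + 1) scale, which understates those of genes with low FPKM.

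Sirt1, an NAD-dependent protein deacetylase, fell in Sirt1KO ESC from 25.8 ± 0.412 to 15.5 ± 0.196 FPKM (log2 fold change -0.71 ± 0.04, limma, Benjamini-Hochberg adjusted p = 5.76e-09). It was at 15.6 ± 0.492 FPKM in Sirt1KO Otx2KD ESC and rose to 33.2 ± 1.24 in EpiLC (log2 0.35 ± 0.04). The Sirt1 value covers the whole gene (XLOC_002273, chromosome 10, 62781753 to 62801783, mm9), and the labels do not give the deleted part, so transcript from outside it would be counted here. Otx2, a homeobox transcription factor of the post-implantation epiblast (XLOC_007523, chromosome 14, 49277859 to 49282547), was at 7.38 ± 0.458 FPKM in wild-type ESC and 100.2 ± 3.45 in EpiLC. In Sirt1KO ESC it rose to 27.0 ± 6.36 FPKM (log2 1.72 ± 0.12, adjusted p = 9.21e-08), and in Sirt1KO Otx2KD ESC it fell to 6.07 ± 0.401 FPKM (log2 -1.96 ± 0.12 against Sirt1KO, adjusted p = 4.13e-08). That level did not pass the test against wild-type ESC (log2 -0.25 ± 0.12, adjusted p = 0.103), although it did when only these 2 groups were fitted. The Otx2 level in Sirt1KO replicate 1 was 34.2 FPKM, against 24.6 and 22.2 in the other replicates. Pou5f1, which encodes the pluripotency factor Oct4, stood between 604 and 660.2 FPKM in all groups. Its log2 change in EpiLC was -0.02 ± 0.03 (adjusted p = 0.675), with the other sign (0.19) under quantile normalization. Its rise in Sirt1KO (0.11 ± 0.03, adjusted p = 0.00682) was lost under quantile normalization (0.00) and when unnamed loci entered the tests.

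**Figure D1:**
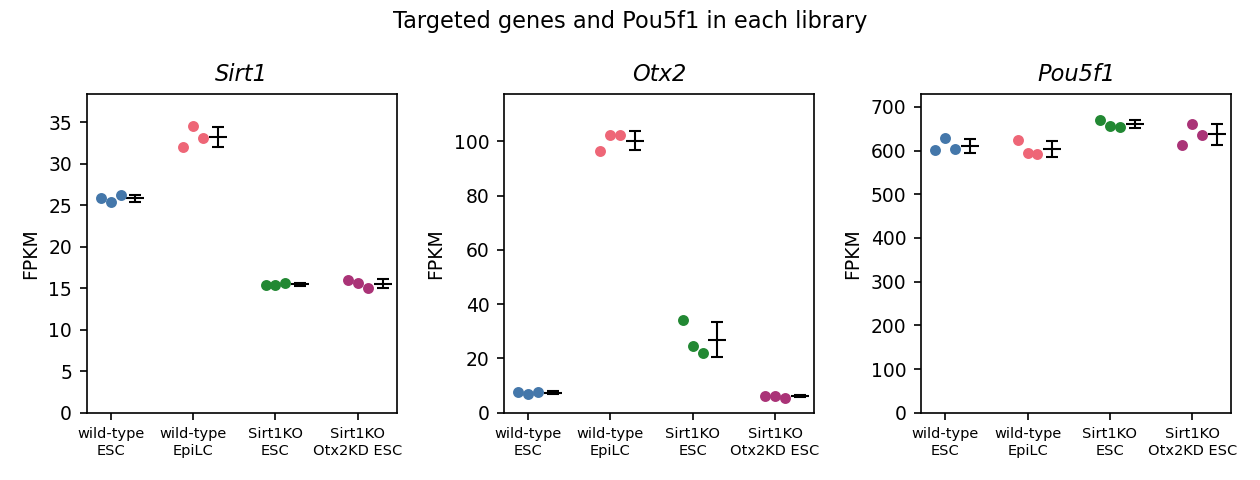
FPKM of Sirt1, Otx2 and Pou5f1 in each library (points) of the 4 groups, with the group mean and SD (black, n = 3). Otx2 averages 100.2 FPKM in EpiLC, 27.0 in Sirt1KO ESC and 6.07 in Sirt1KO Otx2KD ESC.

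Whole chromosomes differed between wild-type ESC and the 3 other groups, and this holds beside every comparison with wild-type ESC below. The median log2 fold change of the 680 genes tested on chromosome 8 was 0.40 in EpiLC, 0.46 in Sirt1KO and 0.36 in Sirt1KO Otx2KD. The 1039 genes of chromosome 11 had medians of -0.46, -0.49 and -0.39 in the same order, and 84.8% of them lay below wild-type ESC in Sirt1KO. Both chromosomes passed camera in each of these comparisons, also with an estimated correlation (chromosome 11 in Sirt1KO: adjusted p = 1.57e-22, and 1.97e-05 with an estimated correlation). The Y-linked genes Eif2s3y, a subunit of translation initiation factor eIF2, and Ddx3y, an RNA helicase, were at 28.9 ± 1.48 and 14.4 ± 0.449 FPKM in wild-type ESC. They were at 4.52 ± 0.857 and 2.81 ± 0.309 FPKM in EpiLC and at 0.0961 and 0.0197 in Sirt1KO. In Sirt1KO Otx2KD they were at 0.417 and 0.267 FPKM, higher than in Sirt1KO (log2 0.35 ± 0.14 and 0.31 ± 0.08, adjusted p = 0.0394 and 0.00408). Between Sirt1KO Otx2KD and Sirt1KO, the medians of chromosomes 8 and 11 were -0.10 and 0.07, and neither passed camera (adjusted p = 0.119 for each). Chromosome 6 had a smaller shift that passed in Sirt1KO (median 0.15, adjusted p = 0.0118, and 0.00617 with an estimated correlation) and Sirt1KO Otx2KD (0.19, adjusted p = 3.99e-06, and 0.00021 with an estimated correlation) but not in EpiLC (adjusted p = 0.666). Chromosome X passed in Sirt1KO Otx2KD (median -0.13, adjusted p = 0.00271, but 0.0721 with an estimated correlation).

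**Figure D2:**
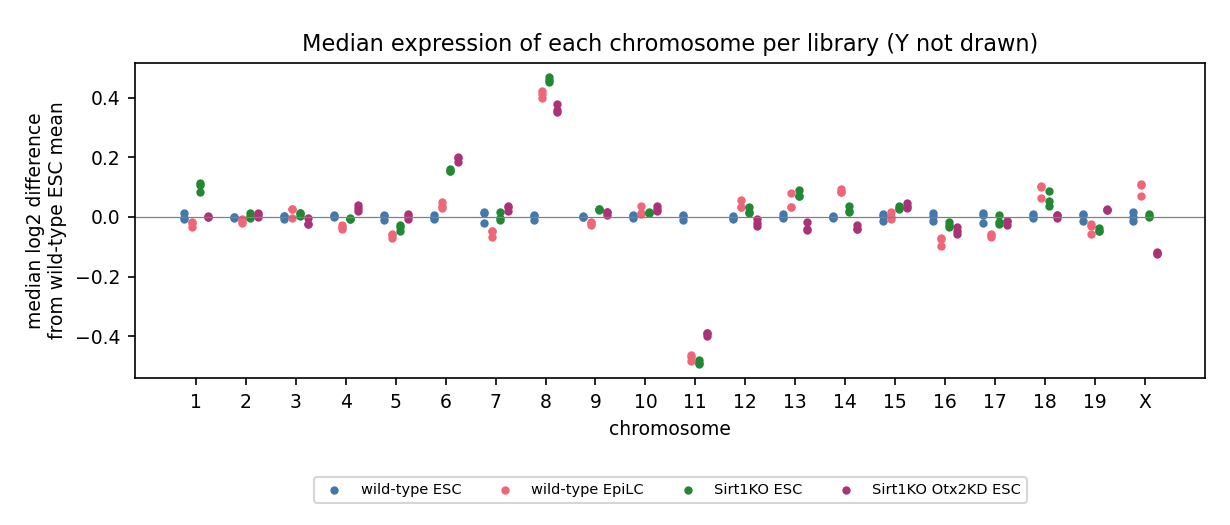
Median log2 difference of the tested genes of each chromosome from the wild-type ESC mean, with a point per library coloured by group. All libraries of EpiLC, Sirt1KO and Sirt1KO Otx2KD lie above wild-type ESC on chromosome 8 and below it on chromosome 11.

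The comparison of EpiLC with wild-type ESC asks what differs between the naive and the primed-like state, and holds the chromosome shifts as well. The media also differ (MEK and GSK3 inhibitors in ESC, Fgf2 and Activin A in EpiLC), so state and medium cannot be told apart. Genes of the naive network fell: Tfcp2l1, a transcription factor that sustains naive self-renewal, went from 84.1 ± 2.58 to 7.91 ± 0.298 FPKM (log2 -3.26 ± 0.07), and the T-box factor Tbx3 fell as well (log2 -3.79 ± 0.06). Prdm14, a repressor of FGF signalling and DNA methylation, fell from 31.9 ± 0.709 to 1.13 ± 0.132 FPKM (log2 -3.95 ± 0.07), and the maternal factor Dppa3 fell to 36.3 from 232 FPKM. Primed genes rose: the de novo DNA methyltransferase Dnmt3b went from 17.7 ± 1.22 to 478 ± 5.94 FPKM (log2 4.68 ± 0.13), its cofactor Dnmt3l from 5.68 ± 0.572 to 229 ± 12.0 (log2 5.11 ± 0.11), and the POU factor Pou3f1 from 1.34 to 33.0. With limma, 4410 genes were higher and 4780 lower in EpiLC (Benjamini-Hochberg adjusted p under 0.05), and 804 and 1057 of these by at least 1 log2 unit. The libraries of the groups did not overlap for 9457 genes (76.8%, where chance gives 10%).

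Of the 20 naive pluripotency genes tested, 1 rose and 19 fell (camera adjusted p = 4.62e-09, adjusted p = 0.235 with an estimated correlation). The naive gene that rose was Gbx2, a homeobox factor (log2 0.96), named after its value was seen. Among 18 primed and formative genes, 15 rose and 1 fell (camera adjusted p = 1.86e-05, adjusted p = 0.281 with an estimated correlation), including Dnmt3a (log2 4.66 ± 0.13) and the forkhead factor Foxp1 (2.07 ± 0.07). Of 14 general pluripotency genes, 8 rose and 4 fell (camera adjusted p = 0.193), with rises of Utf1 from 36.8 to 412 FPKM and of the RNA-binding protein Lin28a from 20.6 to 195. In the LIF-STAT3 response list, 1 rose and 9 fell of 10 (camera adjusted p = 0.0012, adjusted p = 0.235 with an estimated correlation), among them Socs3, the feedback inhibitor of the pathway (log2 -2.27 ± 0.07), and Stat3 itself (-1.49 ± 0.06). In the FGF-ERK response list, 11 rose and 3 fell of 15 (camera adjusted p = 0.00353, adjusted p = 0.281 with an estimated correlation). Its feedback inhibitors Spry4 (log2 4.22 ± 0.11) and Dusp6 (3.48 ± 0.15) and the ETS factor Etv4 (5.25 ± 0.14) rose. Of 8 BMP response genes, 0 rose and 6 fell, with the inhibitors of differentiation Id2 (log2 -1.63 ± 0.10) and Id3 (-1.49 ± 0.11) among them. That list lay close to the threshold (camera adjusted p = 0.0485, adjusted p = 0.235 with an estimated correlation) and missed it without wild-type ESC replicate 1 (adjusted p = 0.0584) or 2 (0.05), or without EpiLC replicate 2 (0.0526) or 3 (0.0593), and with a pseudocount of 0.1 (0.0562).

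Metabolic genes and markers of cell type moved as well. Of 20 cholesterol synthesis genes, 16 rose and 2 fell (camera adjusted p = 0.000122), the list that also passed with an estimated correlation (adjusted p = 0.0445). Lanosterol synthase Lss went from 24.3 ± 1.55 to 88.3 ± 0.289 FPKM and the mevalonate pathway enzyme Mvd from 32.3 ± 2.27 to 105 ± 4.19. Of 28 oxidative phosphorylation genes, 1 rose and 22 fell (camera adjusted p = 0.00161, adjusted p = 0.281 with an estimated correlation), including falls of the cytochrome oxidase subunit Cox5a (log2 -1.03 ± 0.05). In the integrated stress response list, 11 rose and 2 fell of 15 (camera adjusted p = 0.0485, adjusted p = 0.466 with an estimated correlation), a call that was lost without wild-type ESC replicate 1 (adjusted p = 0.0584) or 2 (0.05) and without EpiLC replicate 1 (0.0581) or 3 (0.0525). Median-of-ratios scaling (0.0503) and removal of chromosome medians (0.0558) ended it too. Epithelial genes gave 8 rises and 2 falls among 12 (camera adjusted p = 0.0387, adjusted p = 0.425 with an estimated correlation), with the adhesion molecule Epcam at log2 2.05 ± 0.07 and the splicing regulator Esrp1 at 2.94 ± 0.12, but quantile normalization ended this call (adjusted p = 0.0534), as did removing chromosome medians (0.075). The genes with the largest falls included the aquaporin Aqp3 (log2 -5.57 ± 0.06), the autophagy receptor Calcoco2 (-5.82 ± 0.09) and creatine kinase Ckb (-4.87 ± 0.05). Mt4, a metallothionein, was at 85.0 ± 15.2 FPKM in wild-type ESC and listed at 0 in all 3 EpiLC libraries. Fibroblast and feeder cell markers, in a list fixed for other cells the cultures could hold, gave 2 rises and 9 falls among 14 (camera adjusted p = 0.124). Type III collagen Col3a1 fell among them from 36.3 ± 2.88 to 15.5 ± 0.387 FPKM. Lists that did not pass camera gave 11 rises and 7 falls among 20 glycolysis genes (camera adjusted p = 0.438), 9 rises and 8 falls among 20 p53 targets (0.955), 6 rises and 2 falls among 11 genes of the DNA methylation machinery (0.0909, 0.0413 under quantile normalization and 0.271 with an estimated correlation), 2 rises and 6 falls among 9 Wnt response genes (0.223), 5 rises and 4 falls among 9 Nodal and Activin response genes (0.82) and 3 rises and 5 falls among 10 mesenchymal genes (0.668). The median and mean of the Nodal and p53 lists had opposite signs. Counts adjusted over the list alone were the same as those over all genes, except for 1 more fall in each of oxidative phosphorylation (23), integrated stress response (3) and mesenchymal genes (6). Of the genes named for EpiLC, Mt4 and Mvd lie on chromosome 8 and Calcoco2, Etv4, Socs3 and Stat3 on chromosome 11.

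**Figure D3:**
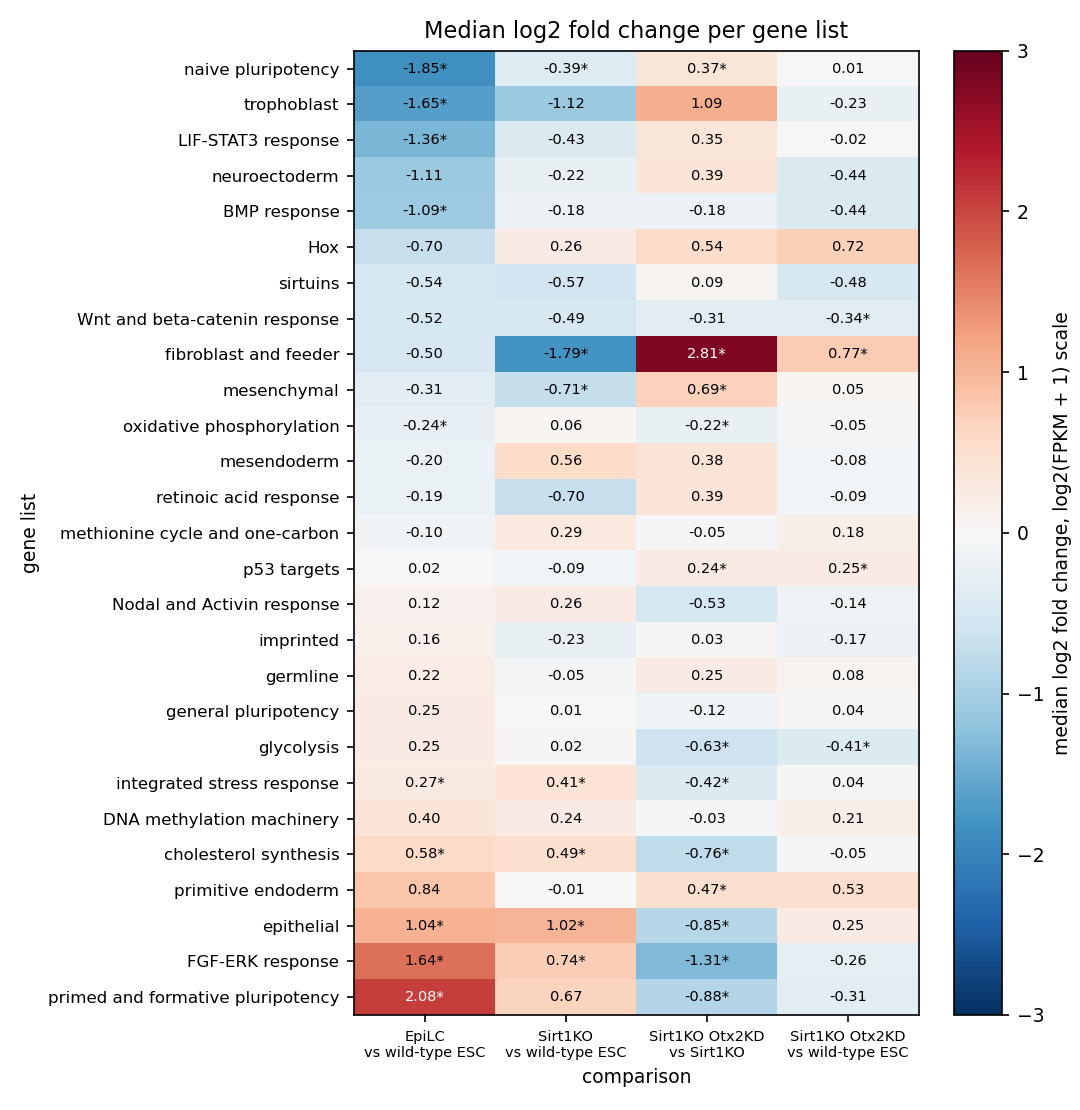
Median log2 fold change of the tested members of 27 gene lists (vertical axis) in 4 comparisons (horizontal axis), with an asterisk where the camera adjusted p was under 0.05 at the preset correlation. Naive genes have a median of -1.85 in EpiLC, -0.39 in Sirt1KO and 0.37 in Sirt1KO Otx2KD against Sirt1KO.

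The comparison of Sirt1KO with wild-type ESC asks whether loss of Sirt1 shifts naive cells toward the primed state. Several primed genes and ERK targets rose in culture conditions that hold the naive state: Dnmt3l went from 5.68 ± 0.572 to 85.7 ± 15.1 FPKM (log2 3.69 ± 0.11, adjusted p = 7.29e-11), Dnmt3b from 17.7 ± 1.22 to 113 ± 26.8, and Pou3f1 from 1.34 to 9.93. The ERK phosphatase Dusp4 rose (log2 3.83 ± 0.20), as did Etv4 (3.16 ± 0.14). Naive genes split: Dppa3 fell from 232 ± 6.78 to 74.5 ± 4.85 FPKM and the nuclear receptor Nr0b1 from 60.4 ± 1.31 to 30.7 ± 2.42, while Klf4 rose from 54.4 ± 1.94 to 108 ± 5.51 and Tfcp2l1 from 84.1 ± 2.58 to 150.3 ± 16.2. With limma, 3987 genes were higher and 4023 lower (adjusted p under 0.05), 336 and 602 of them by at least 1 log2 unit. The libraries did not overlap for 8434 genes (68.5%, chance 10%).

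Of the 20 naive pluripotency genes, 4 rose and 13 fell (camera adjusted p = 0.0445, adjusted p = 0.525 with an estimated correlation). This call was lost without wild-type ESC replicate 1 (adjusted p = 0.0551) or 3 (0.0518) or without Sirt1KO replicate 1 (0.0749). Of 18 primed and formative genes, 11 rose and 6 fell (camera adjusted p = 0.258). The Wnt effector Lef1 (log2 -1.97 ± 0.11) and the growth factor binding protein Igfbp2 (-1.07 ± 0.05) were among those that fell. In the FGF-ERK response list, 11 rose and 2 fell of 15 (camera adjusted p = 0.0256, adjusted p = 0.366 with an estimated correlation), including the ERK pathway inhibitor Spred1 (log2 1.44 ± 0.08) and cyclin D1, Ccnd1 (0.81 ± 0.05). General pluripotency genes gave 6 rises and 6 falls among 14 (camera adjusted p = 0.996). Lin28a rose from 20.6 ± 0.509 to 92.0 ± 13.3 FPKM and Sox2 fell from 263 ± 17.6 to 169 ± 6.81. In the LIF-STAT3 list, 2 rose and 7 fell of 10 (camera adjusted p = 0.073), including the kinase Pim1 (log2 -0.79 ± 0.05).

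Cholesterol synthesis genes rose in Sirt1KO as in EpiLC, with 15 rises and 2 falls among 20 (camera adjusted p = 0.000226, adjusted p = 0.0539 with an estimated correlation). The methylsterol oxidase Sc4mol went from 91.4 ± 2.49 to 248 ± 1.21 FPKM and Lss from 24.3 ± 1.55 to 51.4 ± 3.05. In the integrated stress response list, 9 rose and 2 fell of 15 (camera adjusted p = 0.0445, adjusted p = 0.523 with an estimated correlation), with its transcription factor Atf4 at log2 0.41 ± 0.03. That call was lost without wild-type ESC replicate 1 (adjusted p = 0.0551) or Sirt1KO replicate 1 (0.0819), and with chromosome medians removed (0.0531). Epithelial genes gave 10 rises and 0 falls among 12 (camera adjusted p = 0.000226, adjusted p = 0.235 with an estimated correlation): the tight junction genes Cldn6 (log2 1.59 ± 0.07) and Cldn7 (2.37 ± 0.13) and the keratin Krt18 (2.60 ± 0.13) rose. Mesenchymal genes gave 2 rises and 8 falls among 10 (camera adjusted p = 0.0429, adjusted p = 0.235 with an estimated correlation), with vimentin, Vim, at log2 -0.80 ± 0.07 and the repressor of epithelial genes Zeb1 at -0.78 ± 0.07. Fibroblast and feeder markers fell together, 13 of 14 (camera adjusted p = 5.14e-06, adjusted p = 0.235 with an estimated correlation). Col3a1 dropped from 36.3 ± 2.88 to 2.10 ± 0.0896 FPKM and the type I collagen chain Col1a1 from 38.2 ± 5.80 to 1.81 ± 0.507. Among other large changes, carbonic anhydrase Car4 (log2 4.20 ± 0.18), the POU factor Pou2f3 (3.10 ± 0.09) and transglutaminase Tgm1 (3.22 ± 0.12) rose, and the proneural factor Neurog1 (-4.11 ± 0.11) and the deubiquitinase Usp26 (-4.23 ± 0.09) fell. Of 7 sirtuin genes, 1 rose and 4 fell (camera adjusted p = 0.0674), Sirt1 and Sirt6 (-0.81 ± 0.07) included. Glycolysis (7 rose and 6 fell of 20, camera adjusted p = 0.996), p53 targets (8 rose and 10 fell of 20, 0.996), oxidative phosphorylation (12 rose and 5 fell of 28, 0.226) and BMP response genes (2 rose and 3 fell of 8, 0.396) did not pass. The camera direction of glycolysis, p53 targets and general pluripotency differed from the sign of their median or mean, and under quantile normalization the medians of glycolysis (0.02) and general pluripotency (0.01) turned to -0.03 and -0.04. Of 15 genes of the methionine cycle and one-carbon metabolism, 8 rose and 3 fell (camera adjusted p = 0.211), with the mitochondrial enzyme Mthfd1l at log2 0.72 ± 0.05. Counts adjusted over the list alone differed from those over all genes in the integrated stress response, where 10 rose. Dusp4 and Sc4mol lie on chromosome 8, and Etv4, Cldn7, Car4 and Col1a1 on chromosome 11.

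The comparison of Sirt1KO Otx2KD with Sirt1KO ESC asks what differs after Otx2 knockdown in cells that carry the Sirt1 knockout, where the labels give neither the method nor its control. Primed and ERK-responsive genes fell: Dnmt3l went from 85.7 ± 15.1 to 12.6 ± 1.08 FPKM (log2 -2.66 ± 0.11), Dnmt3b from 113 ± 26.8 to 25.1 ± 1.08, Pou3f1 from 9.93 to 2.28 and Ccnd1 from 42.2 ± 1.87 to 6.57 ± 0.415. Dppa3 rose from 74.5 ± 4.85 to 216 ± 2.61 FPKM, while Klf4 fell from 108 ± 5.51 to 49.1 ± 1.33. The hormone precursor Trh fell most, from 248 ± 12.2 to 8.46 ± 1.21 FPKM (log2 -4.73 ± 0.08, adjusted p = 8.33e-14). Among the genes with the largest rises, Col3a1 went from 2.10 ± 0.0896 to 75.2 ± 0.761 FPKM (log2 4.62 ± 0.05), periostin, Postn, from 0.313 ± 0.0726 to 29.4 ± 1.64, and lysyl oxidase, Lox, from 1.65 ± 0.295 to 39.4 ± 1.30. With limma, 3830 genes were higher and 3877 lower (adjusted p under 0.05), 471 and 232 of them by at least 1 log2 unit, and the libraries did not overlap for 8285 genes (67.2%, chance 10%).

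Naive pluripotency genes gave 13 rises and 4 falls among 20 (camera adjusted p = 0.0338, adjusted p = 0.501 with an estimated correlation), with Nr0b1 (log2 0.83 ± 0.06) and Prdm14 (0.74 ± 0.07) among those that rose. Of 18 primed and formative genes, 4 rose and 13 fell (camera adjusted p = 0.00852, adjusted p = 0.424 with an estimated correlation), including the neural factor Sox11 (log2 -1.04 ± 0.06). In the FGF-ERK response list, 1 rose and 11 fell of 15 (camera adjusted p = 0.000239, adjusted p = 0.158 with an estimated correlation), among them Dusp6 (log2 -2.16 ± 0.15) and the immediate early gene Fos (-1.63 ± 0.10). Nodal and Activin response genes gave 1 rise and 5 falls among 9 (camera adjusted p = 0.0501). The Nodal inhibitors Lefty1 (log2 -1.53 ± 0.06) and Lefty2 (-1.15 ± 0.07) fell. This list passed under both other scalings (adjusted p = 0.0493 and 0.0496) and without Sirt1KO replicate 1 (0.0454), 2 (0.0469) or 3 (0.0482) or Sirt1KO Otx2KD replicate 2 (0.0381) or 3 (0.0388). It did not pass with an estimated correlation (0.159), a pseudocount of 0.1 (0.0503) or chromosome medians removed (0.0777).

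Cholesterol synthesis fell as a group, with 1 rise and 14 falls among 20 (camera adjusted p = 3.12e-06), and passed with an estimated correlation too (adjusted p = 0.015). Sc4mol went from 248 ± 1.21 to 114 ± 2.23 FPKM and squalene epoxidase, Sqle, from 86.4 ± 2.19 to 50.3 ± 0.985. Of 20 glycolysis genes, 3 rose and 14 fell (camera adjusted p = 0.000239, adjusted p = 0.136 with an estimated correlation). Lactate dehydrogenase Ldha fell from 500.2 ± 17.6 to 244 ± 4.98 FPKM, and the lactate exporter Slc16a3 from 40.8 ± 4.87 to 6.79 ± 0.269. Oxidative phosphorylation gave 4 rises and 19 falls among 28 (camera adjusted p = 0.0112, adjusted p = 0.301 with an estimated correlation), with the complex I subunit Ndufs1 at log2 -0.53 ± 0.04, and the integrated stress response 2 rises and 11 falls among 15 (camera adjusted p = 0.0161, adjusted p = 0.367 with an estimated correlation), with Atf4 at -0.43 ± 0.03. Of 20 p53 targets, 12 rose and 3 fell (camera adjusted p = 0.0338, adjusted p = 0.157 with an estimated correlation), with the exonuclease Aen at 0.96 ± 0.05, whereas the proapoptotic gene Pmaip1 fell (-1.46 ± 0.10). Fibroblast and feeder markers gave 13 rises and 0 falls among 14 (camera adjusted p = 3.62e-09, adjusted p = 0.136 with an estimated correlation). Mesenchymal genes gave 8 rises and 1 fall among 10 (camera adjusted p = 0.0188, adjusted p = 0.144 with an estimated correlation), with Zeb1 at 0.98 ± 0.07, and epithelial genes 1 rise and 11 falls among 12 (camera adjusted p = 0.000934, adjusted p = 0.198 with an estimated correlation), with Epcam at -1.16 ± 0.07. Primitive endoderm genes gave 6 rises and 0 falls among 8 (camera adjusted p = 0.0256, adjusted p = 0.158 with an estimated correlation), and those that rose included the basement membrane genes Lamb1 (log2 0.44 ± 0.05) and Col4a1 (0.96 ± 0.09). The DNA methylation machinery gave 3 rises and 5 falls among 11 (camera adjusted p = 0.518), LIF-STAT3 6 rises and 2 falls among 10 (0.121), BMP response 3 rises and 3 falls among 8 (0.961) and Wnt response 3 rises and 5 falls among 9 (0.456). The BMP median and mean had opposite signs. Adjusted over the list alone, 5 oxidative phosphorylation genes rose, and no other count differed. Sc4mol and Col4a1 lie on chromosome 8 and Slc16a3 on chromosome 11.

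**Figure D4:**
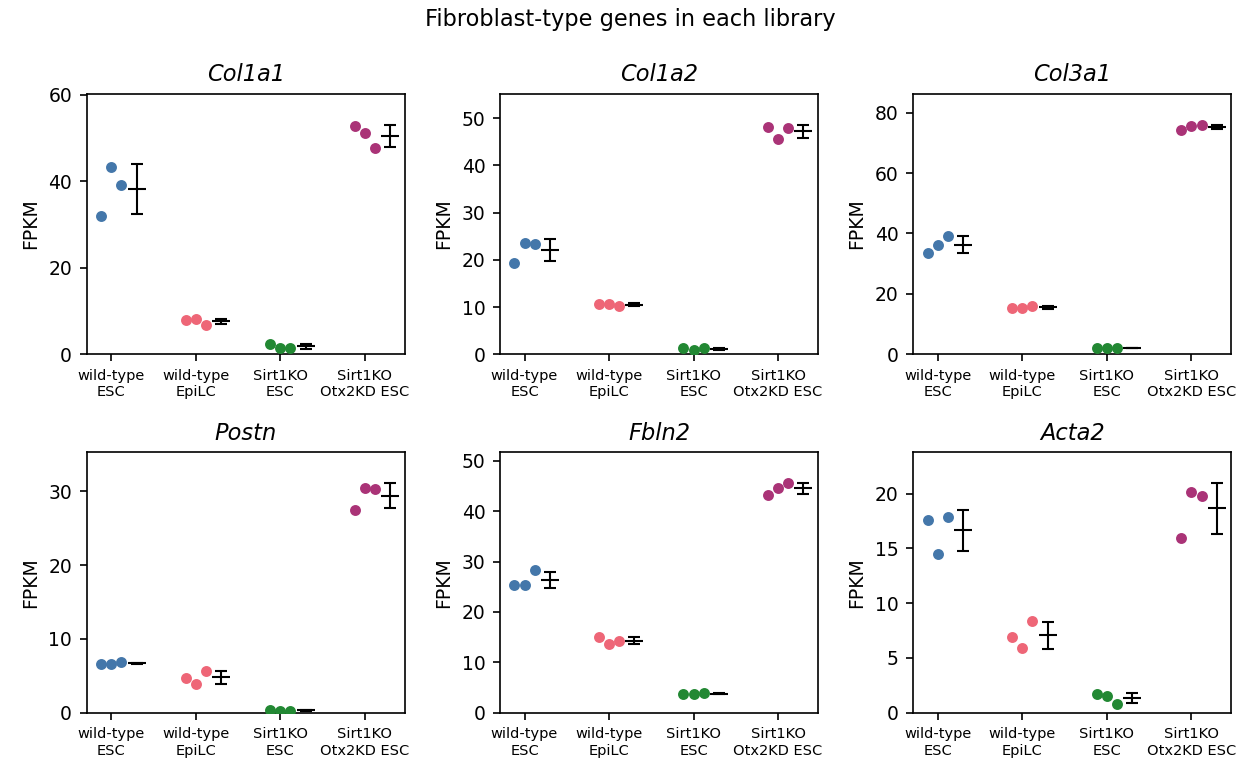
FPKM of 6 genes typical of fibroblasts in each library (points) of the 4 groups, with the group mean and SD (black, n = 3). All 6 are among the 10 list members whose Sirt1KO level was under 10% of that in Sirt1KO Otx2KD. Members without that pattern are not drawn, such as Tagln (9.59, 10.95 and 13.22 FPKM in wild-type ESC, Sirt1KO and Sirt1KO Otx2KD). Col3a1 averages 36.3 FPKM in wild-type ESC, 2.10 in Sirt1KO and 75.2 in Sirt1KO Otx2KD.

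Set against each other, the effects in EpiLC and in Sirt1KO, both taken against wild-type ESC, went the same way for many genes. Those in Sirt1KO Otx2KD against Sirt1KO went the opposite way for many. Changes of at least 1 log2 unit in both EpiLC and Sirt1KO were shared by 161 genes that were higher, Dnmt3b among them, and 371 that were lower, Dppa3 among them, where independent lists would share 21.9 and 51.6. At adjusted p under 0.05, 2527 genes were higher in both EpiLC and Sirt1KO and 2790 lower in both, where independent lists would share 1427 and 1561. Opposite calls numbered 509 and 665, where independent lists would share 1440 and 1547. Across the 12320 genes, which are not independent replicates, Pearson's r between these effects was 0.593 and Spearman's rho 0.570. The covariance was 0.319, against 0.0304 in simulations of unchanged groups that share the wild-type ESC libraries, a difference of 0.288 (the simulated r was 0.496). Part of the excess of shared calls may come from the shared controls, and 3 libraries cannot be split so that each part keeps 2. The Otx2 knockdown effect shares no library with the transition. Its r with the transition was -0.448 and its rho -0.454 (covariance -0.213), and 2208 genes were higher in EpiLC but lower after knockdown, where independent lists would share 1388.

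Of 8010 genes changed in Sirt1KO, 5206 (65.0%) changed the opposite way and 639 the same way after Otx2 knockdown. Of the opposite calls, 2583 were higher and 2623 lower in Sirt1KO, where independent lists would share 1255 and 1251. Same-way calls numbered 320 and 319, where independent lists would share 1239 and 1266. Both comparisons share the Sirt1KO libraries, and their r was -0.695, against -0.499 in simulations of unchanged groups. Simulations without a knockdown effect averaged 0.04 opposite calls, but almost no gene is then called after knockdown, so this count cannot judge direction. Among the 938 genes that had changed by at least 1 log2 unit in Sirt1KO, 820 (87.4%) went the opposite way, Dnmt3l, Dnmt3b and Col3a1 included, and 21 the same way. Many moved back only in part, as 619 of the 938 (66.0%) were still changed in the same direction against wild-type ESC. A further measure places each library on the axis from wild-type ESC (0%) to EpiLC (100%) over the 1057 and 804 genes with the larger transition changes. Sirt1KO lay at 43.7 ± 5.36% and Sirt1KO Otx2KD at 10.2 ± 0.681% (SD, n = 3), with Sirt1KO replicate 1 at 49.6%. The exact permutation test between these groups gave p = 0.1, as did that between Sirt1KO and wild-type ESC, which is the smallest p that 3 against 3 libraries allow. Without chromosomes 8, 11 and Y the positions were 40.9 ± 5.30% and 6.24 ± 0.423%. The position pools genes higher and genes lower in EpiLC, and Sirt1KO differed between them. On the FPKM scale, Sirt1KO reached a median of 26.4% of the EpiLC change for genes higher in EpiLC and 61.4% for genes lower. These medians cover axis genes with at least 5 FPKM in the higher group.

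**Figure D5:**
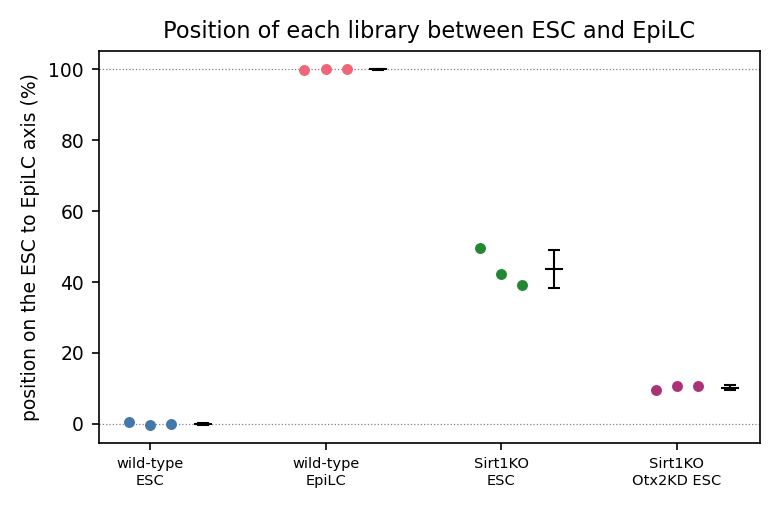
Position of each library (points) on the axis from wild-type ESC (0%) to EpiLC (100%), with the group mean and SD (black, n = 3). The ends are fixed by construction, Sirt1KO lies at 43.7% and Sirt1KO Otx2KD at 10.2%. Genes higher and genes lower in EpiLC are pooled, although Sirt1KO moved further for those lower.

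Compared with wild-type ESC, Sirt1KO Otx2KD cells had lower glycolytic and higher fibroblast-type expression. Slc16a3 was at 43.4 ± 1.26 FPKM in wild-type ESC and 6.79 ± 0.269 in Sirt1KO Otx2KD (log2 -2.51 ± 0.07, adjusted p = 3.48e-11), and glycolysis genes gave 1 rise and 16 falls among 20 (camera adjusted p = 1.77e-06, adjusted p = 0.0868 with an estimated correlation). Fibroblast and feeder markers gave 12 rises and 1 fall among 14 (camera adjusted p = 0.000248, adjusted p = 0.248 with an estimated correlation), with Postn at log2 1.98 ± 0.09. Of 20 p53 targets, 11 rose and 2 fell (camera adjusted p = 0.0154, adjusted p = 0.122 with an estimated correlation), with the Akt inhibitor Phlda3 at 0.93 ± 0.08. Wnt response genes gave 1 rise and 5 falls among 9 (camera adjusted p = 0.0294, adjusted p = 0.162 with an estimated correlation), but Axin2, Tcf7 and Notum (like Slc16a3) lie on chromosome 11, and the call was lost with chromosome medians removed (adjusted p = 0.207). Lef1 fell from 11.3 ± 0.982 to 0.915 ± 0.242 FPKM, and the glutathione transferase Gsto1 rose from 67.9 ± 3.11 to 267 ± 10.8. Naive pluripotency genes gave 7 rises and 5 falls among 20 (camera adjusted p = 0.84) and primed genes 4 rises and 10 falls among 18 (0.119). The naive median was 0.01 and turned negative (-0.02) under quantile normalization. Adjusted over the list alone, 13 p53 targets rose, and the naive, primed, glycolysis, fibroblast and Wnt counts did not differ. With limma, 3333 genes were higher and 3306 lower (adjusted p under 0.05), 183 and 216 of them by at least 1 log2 unit, and the libraries did not overlap for 7554 genes (61.3%, chance 10%). Of 8010 genes changed in Sirt1KO, 3894 (48.6%) were still changed in the same direction against wild-type ESC.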

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

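All tests in this part were chosen after the result was seen. Among the 4778 loci without a gene name, 13 reached at least 5 FPKM in all 6 Sirt1KO-derived libraries and stayed, in all 6 wild-type libraries, under 10% of the lowest Sirt1KO-derived value of the same locus, while 0 showed the converse. The strongest was a locus of 65 bp on chromosome 10 (16489284 to 16489348, mm9), at 20545 ± 730.0 FPKM (SD, n = 3) in Sirt1KO ESC and 16868 ± 1693 in Sirt1KO Otx2KD ESC, and listed at 0 in all wild-type ESC and EpiLC libraries. A neighbouring locus of 138 bp (16488941 to 16489078) was at 4706 ± 240.0 FPKM in Sirt1KO and 8.46 ± 14.7 in wild-type ESC. A locus of 65 bp on chromosome X (111166231 to 111166295) was at 2212 ± 987 FPKM in Sirt1KO and listed at 0 in wild-type libraries. FPKM of loci this short rests on few positions and overstates abundance. What these loci are was not tested, since the files give no sequence and no name for them. Groups of 3 libraries were not tested for single libraries that stand apart.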

How the results depend on the processing

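The settings with unnamed loci, without chromosomes 8, 11 and Y, with chromosome medians removed, and the lists under quantile normalization or with a library left out were chosen after the result was seen. A minimum of 1 log2 unit left 804 genes higher and 1057 lower in EpiLC, 336 and 602 in Sirt1KO, 471 and 232 in Sirt1KO Otx2KD against Sirt1KO, and 183 and 216 against wild-type ESC. With it on the Sirt1KO change alone, 820 of 938 genes went the opposite way after Otx2 knockdown at adjusted p under 0.05, and 619 were still changed in the same direction against wild-type ESC. With it on both changes, 133 genes higher and 272 lower in Sirt1KO went the opposite way. Sirt1 (-0.705) did not reach this minimum in Sirt1KO. With an estimated correlation, 1, 0, 1 and 0 lists passed in these comparisons, and with fry 27, 24, 27 and 22. Unlike camera, fry does not compare a list with the other genes. As 53.9% to 74.6% of all tested genes were called per comparison, most lists would pass it, so its counts answer another question.

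The correlation of transition and Sirt1KO effects (0.593) was 0.5537 with unnamed loci, 0.5605 without chromosomes 8, 11 and Y and 0.5753 with chromosome medians removed. Leaving out each library gave 0.5574 (without Sirt1KO replicate 1) to 0.6074. That of transition and Otx2 knockdown effects (-0.448) was -0.416 with no filter, -0.5093 without short non-coding genes and -0.3954 with unnamed loci, and ranged from -0.4646 (without Sirt1KO replicate 3) to -0.4084 (without Sirt1KO replicate 1). The cause of these shifts was not tested.

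The direction of Pou5f1 in EpiLC was reversed under quantile normalization (0.188). With chromosome medians removed, Cox4i1 (-0.117) and Sc4mol (-0.059) were reversed in Sirt1KO Otx2KD against wild-type ESC. The replicate block gave 4363 genes higher and 4717 lower in EpiLC and 3929 and 3964 in Sirt1KO, and with it the BMP and integrated stress response lists no longer passed in EpiLC (adjusted p = 0.053 for each). Libraries of the same replicate number in different groups correlated between -0.107 and 0.17 (18 pairs), and 3 of 12 libraries correlated best with their own number. The labels do not say that replicate numbers pair the samples. Count-based tests were not run, since no counts are given.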

Other observations

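The tests of the 3 patterns weighed here were chosen after the result was seen, while the counts of other splits were set out before they were run. Imprinted genes went both ways and did not pass camera as a list, although some members moved together. In Sirt1KO, the noncoding RNA H19 fell from 40.2 ± 4.78 to 5.83 ± 0.783 FPKM (log2 -2.60 ± 0.09), its neighbour the growth factor Igf2 from 16.9 ± 1.10 to 1.68 ± 0.187, and the noncoding RNA Meg3 by log2 -4.46 (limma, adjusted p = 2.41e-13). After Otx2 knockdown H19 rose again to 41.5 ± 2.41 FPKM and Igf2 to 20.0 ± 1.12, and the Meg3 log2 change was 2.78. The fibroblast and feeder markers took the same course, with 13 of 14 lower in Sirt1KO and 13 higher after knockdown. Of 20 imprinted genes, 10 rose and 9 fell in EpiLC (camera adjusted p = 0.711), 5 rose and 10 fell in Sirt1KO (0.196) and 9 rose and 6 fell after knockdown (0.36), where the median of 0.03 turned to -0.01 under quantile normalization. Germline genes gave 9 rises and 7 falls among 16 in EpiLC (0.649) and 6 rises and 5 falls in Sirt1KO (0.906), and the RNA-binding protein Dazl fell in both (log2 -1.54 ± 0.09 and -1.71 ± 0.09) and rose after knockdown (1.36 ± 0.09).

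Trophoblast genes fell in EpiLC, with 1 rise and 5 falls among 6 (camera adjusted p = 0.0387, adjusted p = 0.235 with an estimated correlation), led by the transcription factors Tfap2c (log2 -3.57 ± 0.07) and Gata2 (-2.90 ± 0.07). In Sirt1KO 2 rose and 4 fell (camera adjusted p = 0.191). Retinoic acid response genes gave 3 rises and 4 falls among 9 in EpiLC (0.711), 1 rise and 6 falls in Sirt1KO (0.109) and 5 rises and 0 falls after knockdown (0.107), with the meiotic gatekeeper Stra8 at log2 -2.01 ± 0.14 in Sirt1KO and 1.99 ± 0.14 after knockdown. Of 3 mesendoderm genes, 1 rose and 2 fell in EpiLC (camera adjusted p = 0.668), where the organizer gene Gsc went from 12.6 ± 0.996 to 0.196 ± 0.108 FPKM, and 2 rose and 1 fell in Sirt1KO (0.834, median and mean of opposite sign). Neuroectoderm genes gave 2 rises and 3 falls among 5 in EpiLC (0.486) and 1 rise and 3 falls in Sirt1KO (0.388). Neuronal tubulin Tubb3 fell in both (log2 -1.96 ± 0.05 and -0.82 ± 0.05). It lies on chromosome 8, whose median moved the other way in both (0.40 and 0.46). Hox genes gave 1 rise and 3 falls among 4 in EpiLC (0.338), and primitive endoderm genes 6 rises and 2 falls among 8 (0.198), with laminin Lamb1 at log2 1.15 ± 0.05.

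The shift of chromosomes 8 and 11 between wild-type ESC and all other groups has 3 explanations that were weighed. A correction for GC content and transcript length left the chromosome 11 median in Sirt1KO at -0.473, from -0.488, which argues against such a bias. In Sirt1KO Otx2KD, which lay near wild-type ESC on the transition axis, that median was 85.6% of its value in EpiLC, which argues against cell state. All 20 blocks of neighbouring genes moved with their chromosome, so different copy numbers of chromosomes 8 and 11 are a candidate explanation, where 2 copies against 3 would give -0.58 in every cell. Whether the wild-type ESC come from other cells than the EpiLC and knockout lines, as their Y-linked expression could also reflect, stays open, since no DNA was measured. The smaller shift of chromosome 6 was not weighed.

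The fibroblast genes low in Sirt1KO and high in Sirt1KO Otx2KD included Col1a1, at 38.2, 1.81 and 50.5 FPKM in wild-type ESC, Sirt1KO and Sirt1KO Otx2KD, and Fbln2, at 26.4, 3.77 and 44.5, and the Y-linked Ddx3y also rose after knockdown, from 0.0197 to 0.267 FPKM. All 14 list members passed the expression filter, and 0 are in another list. Foreign RNA of a fixed makeup predicts the same ratio of Sirt1KO Otx2KD to wild-type ESC for all members, if the cells themselves express none. Over the 10 members whose Sirt1KO level was under 10% of that in Sirt1KO Otx2KD, this log2 ratio had an SD of 0.545. The median SE of 0.107 may reflect technical spread alone, and expression by the cells themselves was not measured. The SD therefore cannot decide on such RNA. Levels set by Otx2 repression alone would be lower in EpiLC, where Otx2 was higher than in Sirt1KO. In EpiLC, 13 of 14 members were higher than in Sirt1KO (median log2 ratio 2.28). Medium and state differ between these groups too, and EpiLC may hold other cells, so repression by Otx2 within Sirt1KO cells stays open. Other cells of changing makeup may explain the 13 members that rose after knockdown, which stays open because no profile of such cells was given and the labels name no sort or feeder layer. An effect of the genotype on these genes is open in the same way.

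For the correlation of Sirt1KO and transition effects, shared wild-type ESC libraries were weighed by the transition and Otx2 knockdown effects, which share no library. Their correlation was -0.448, but it concerns another effect and cannot say how much of the 0.593 comes from the shared libraries. The covariance of 0.319 exceeded the 0.0304 simulated for noise in these libraries. That simulation leaves out any real difference between the wild-type ESC and the other cells. A uniform shift of whole chromosomes as the source is argued against by the correlation of 0.575 that remained with chromosome medians removed. Any effect of such a difference between the cells on single genes stays in that value. A mixture of EpiLC-like cells with cells like these wild-type ESC predicts equal fractions of the EpiLC change in FPKM for both directions. Among genes changed by at least 1 log2 unit with at least 5 FPKM in the higher group, the medians were 26.4% for 554 genes higher in EpiLC (quartiles 11% and 49.2%) and 61.4% for 826 lower (30.9% and 86.6%). They lay 35 percentage points apart with overlapping quartiles. Genes of the shifted chromosomes were not removed, and the wild-type ESC may not match the unmixed cells, so this gap cannot decide on such a mixture. A partial shift of the cells toward the primed state is a hypothesis consistent with these values, found and tested on the same data. Whether it comes from Sirt1 loss or from another difference between the lines stays open, since no rescue or second line was measured.

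With 3 against 3 libraries there are 10 splits, so the share of splits with as many calls is never under 0.1. In each comparison, 1 of 10 splits, the real grouping, gave as many genes (9190 in EpiLC, 8010 in Sirt1KO, 7707 in Sirt1KO Otx2KD against Sirt1KO and 6639 against wild-type ESC), and the highest of the other splits called 1 gene. Every other split mixes the 2 groups, so their difference enters the residual spread and leaves few calls. The low count of those splits was thus set by the design and does not measure chance.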
